A study of Caenorhabditis elegans with 68 samples.

How the data were processed

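Hatched first-stage (L1) larvae of the nematode Caenorhabditis elegans were profiled by RNA sequencing after their mothers had been exposed to 50 or to 300 mM NaCl. Per the labels' protocols, larvae were synchronised without starvation, the RNA fraction above 200 nucleotides was treated with DNase, samples with an RNA integrity number above 8 were used, ribosomal RNA was depleted with RNase H, and the libraries were strand-specific. The submitters' processing notes name the genome builds ce11 and WBcel235 and the program bedtools. The aligner, the counting program, its use of strand and the version of the annotation are not given in the sources used here. Overlapping genes on opposite strands and near-identical gene copies are therefore reported as uncertain.

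The authors deposited 1 table of TPM (a length-normalised share of a library's transcripts), with 30470 lines, of which 20450 were typed as protein-coding, 7687 as ncRNA and 1590 as pseudogenes, and 3 held reporters. TPM summed to between 953862 and 999109 per library. TPM keep no sequencing depth, so the depth of each library is unknown, no counting interval can be given, and the precision of a value was judged from the spread between libraries. Values of 0 are given as listed at 0. The table gives a name beside each gene ID, and 28048 IDs matched a symbol in the reference table. A spreadsheet had turned 11 names into dates, and these took the symbol of their ID. Values of 48 of the 68 samples were used, and 0 columns matched no sample. The other 20 samples, which include 2-cell embryos and a strain in which DROSHA and PASHA can be degraded, are not analysed here.

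Groups followed the labels. Libraries whose titles place them in 1 experiment are called a set, and the sets used here are D to G. Set D held the wild type (WT) and mir-85(n4117), with 2 libraries per group. Set E held progeny of mothers heterozygous for mir-85(n4117) over a balancer chromosome, with 3 libraries per group. Its F1het larvae were heterozygous and its F1KO larvae homozygous for n4117. Set F held mir-85(gcp109), a deletion of the 3p sequence of mir-85, with 4 libraries per group. Set G held the wild type strain N2 and hrg-1(gcp100), in which the mir-85 seed site of hrg-1 was mutated, with 5 libraries per group. The labels call the libraries of a group biological replicates without naming separate cultures, so p-values measure only the spread between these samples. No libraries of a group held identical values, and the highest correlation between replicates was r = 0.982. The lowest was 0.676 in N2 at 300 mM (replicates 3 and 4) and 0.768 in gcp100 at 300 mM (replicates 3 and 5). In the other groups the lowest was 0.926, in gcp109 at 300 mM.

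The set G columns needed a correction, chosen after the data were examined. Behind the 3 reporter lines the values of this set stood 1 to 3 lines away from the names of their genes, for 20693 of 30467 lines. As deposited, mean log2(TPM + 1) of set G correlated across genes with that of the other 28 libraries at r = 0.593, against r = 0.991 between sets D and F. Moved back to their names, they correlated at r = 0.988. The share of ncRNA lines with a mean of at least 10 TPM in set G, a check that uses no other library, went from 9.77% to 1.35%, and was 1.68% in the other libraries. The moved values are reported throughout. The line of hrg-1 lay in a stretch that was not displaced.

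Fold changes were computed on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean level, in 1 fit per set and 1 fit over sets F and G together. The pseudocount of 1 understates the change of genes with low TPM. Genes with at least 1 TPM in at least as many libraries as the smallest group were tested, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A change is said to have passed the test only under this threshold. The test, the samples in each fit, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. For hrg-1 an exact two-sided permutation test of log2(TPM + 1) was added for each of 15 comparisons of 2 groups. The difference of the NaCl responses of 2 genotypes, called an interaction, was tested for hrg-1 by permuting the genotype labels within each NaCl level.

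Named genes followed a fixed rule. In a main comparison these were up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold with a mean of at least 5 TPM in 1 of the groups and no overlap between the groups. In other comparisons the number was 3 and 3. Beside these stood hrg-1, drsh-1, pash-1, vit-1 to vit-6, genes within 10 kb of mir-85 and of hrg-1, and up to 4 members with the smallest p from each list. Not all genes that met the rule are named. Genes named outside the rule are said to be so.

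Gene and marker lists were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, run without standardisation, for whether a list moved on balance in 1 direction. Each list needed at least 3 tested members, and p-values were adjusted over the 27 or 28 lists of a comparison. Camera compares a list with all other genes, fry does not. With the preset correlation 197 list tests passed the threshold, and 6 of these held with the estimated correlation. Fry passed 24 of the 526 list tests, all among the camera calls and in the same direction, namely 10 in N2 and 3 in gcp109 at 300 against 50 mM, 9 in gcp109 against N2 at 300 mM, and 1 each in F1KO at 300 against 50 mM and in F1KO against F1het at 300 mM. Of the 6 that held with the estimated correlation 3 passed fry.

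Groups shared replicate numbers, so fits with the number as a block were planned. The numbers were taken to pair the libraries where same-numbered libraries deviated together, with r above 0.1 for every pair and at least 3 pairs. This held in F1het at 300 against 50 mM (r from 0.106 to 0.168), in F1KO (0.173 to 0.246), in gcp109 (0.493 to 0.547), and between gcp100 and N2 at 50 mM (0.261 to 0.564). The pairing comes from these correlations, since the labels do not say that a number marks a shared day or culture. Each block fit gave every number 1 shared effect over all libraries of the fit. In sets E and G the block therefore also joined groups whose numbers were not taken to pair the libraries.

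The fits were tested on simulated data made from the levels and spreads of these libraries, with 200 genes changed in each of 19 comparisons. In N2 at 300 against 50 mM, 29.9% of genes changed by 1 on the log2 scale were called, 71.6% of those changed by 2 and 87.9% of those changed by 3. In gcp109 these shares were 47.8%, 91.0% and 90.9%, and in WT, with 2 libraries per group, 8.96%, 43.3% and 75.8%. Over the 19 comparisons 2268 changed genes were called, all with the right sign, and 136 unchanged genes were called as well (5.66% of all calls), with up to 15 in 1 comparison, gcp100 against N2 at 300 mM. The simulated noise was normal and independent between genes, with no library set apart from the others. In the real data another split of the libraries of that comparison gave 2538 calls, so the simulated share does not bound false calls here.

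Alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, TPM rescaled by a median ratio over genes with at least 5 TPM in every library, a replicate block, and leaving out each library in turn. Leaving out set G libraries in doubt, and reading set G with its names as deposited, were added after the data were seen. The planned tests of predicted mir-85 sites in 3′ untranslated regions were not run, because no genome sequence was used here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.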

Results

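RNA sequencing of hatched L1 larvae of Caenorhabditis elegans measured how the salt exposure of mothers, and the loss of the microRNA gene mir-85 or of its target site in hrg-1, altered the transcripts of their progeny. The 48 libraries used here formed 14 groups, with 2 libraries per group in set D, 3 in set E, 4 in set F and 5 in set G. Each strain of each set was sampled at a maternal exposure of 50 and of 300 mM NaCl. WT of set D and N2 of set G carry the same strain and genotype labels and are kept apart here by set. All levels are TPM, with mean ± SD over the libraries of a group, and fold changes are log2 differences of log2(TPM + 1) with their standard error (SE). The sequencing depth is unknown, since TPM keep none. In each fit between 14102 and 16327 genes were tested with limma.

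The microRNA gene mir-85 (WBGene00003313) lies on chromosome II at 8393553 to 8393658 on the plus strand of WBcel235. This position falls within an intron of F49E12.8 (WBGene00009901, II 8392568 to 8394305), which is read from the opposite strand. The table used here holds no value for mir-85, so its loss was looked for in its host gene. The noncoding gene F49E12.14 (WBGene00200629, II 8393569 to 8393644), which lies within mir-85 on the opposite strand, was listed at 0 in all 48 libraries and checks nothing. Transcripts of F49E12.8 stood at 3.46 ± 0.141 TPM in WT and 1.44 ± 0.248 in n4117 at 50 mM (n = 2 each), a log2 difference of -0.88 (SE 0.323) that did not pass the test (adjusted p = 1). At 300 mM the levels were 5.16 ± 1.18 and 1.23 ± 0.735 TPM. In gcp109 the level of F49E12.8 was 4.48 TPM at 50 mM, against 4.73 TPM in N2. This gene does not check the gcp109 label, since only the 3p sequence of mir-85 was deleted. The heme transporter gene hrg-1 (WBGene00019830) lies on chromosome X at 4008057 to 4016221 on the minus strand, with its 3′ untranslated region at 4008057 to 4008234. The gene mop-25.1 (X 4012219 to 4022209) overlaps hrg-1 on the opposite strand. Whether reads were counted by strand is not stated, so reads of this pair may not be separated. By limma mop-25.1 was itself lower in N2 at 300 against 50 mM (log2 -0.635, SE 0.162, adjusted p = 0.0313). It was higher in gcp109 than in N2 at 300 mM (log2 0.63, SE 0.156, adjusted p = 0.03785), and it passed in no other comparison.

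Reporter transcripts stood lower in F1KO than in F1het but not at the level of the other sets. The F1KO label names no balancer. The balancer mIn1 carries the insertion mIs14, with green fluorescent protein and sequence of the gene pes-10. Transcripts of pes-10 stood at 83.5 ± 11.9 TPM in F1het and 11.5 ± 6.48 in F1KO at 50 mM, and at 70.04 ± 13.8 and 3.34 ± 0.319 at 300 mM (n = 3 each). In the groups of all other sets pes-10 had means of 0.226 TPM or below. The line named s65cGFP held 965 ± 140 TPM in F1het and 190 ± 103.8 in F1KO at 50 mM, and 572 ± 58.5 and 56.7 ± 13.1 at 300 mM. It was listed at 0 in every library of sets D and F. The lowest F1KO libraries held 3.13 TPM of pes-10 and 41.7 TPM of s65cGFP. The source of these transcripts in F1KO was not tested.

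Levels of hrg-1, which encodes a heme transporter of the intestine, had higher means at 300 than at 50 mM in every strain of sets D, E and F and in gcp100 but not in N2 of set G. In n4117 they stood at 80.2 ± 62.4 against 14.8 ± 2.86 TPM (log2 2.12, SE 0.499, n = 2 each), and in WT of the same set at 12.57 ± 1.11 against 7.65 ± 0.226 TPM (log2 0.65, SE 0.499). In F1het the levels were 39.1 ± 11.3 against 14.9 ± 2.56 TPM (log2 1.304, SE 0.256), and in F1KO 45.7 ± 6.06 against 15.7 ± 5.72 TPM (log2 1.52, SE 0.256, n = 3 each). In gcp109 they were 52.9 ± 19.2 against 20.0 ± 5.76 TPM (log2 1.33, SE 0.264, n = 4 each). In gcp100, whose hrg-1 lacks the mir-85 seed site, they were 33.8 ± 11.5 against 15.3 ± 5.37 TPM (log2 1.11, SE 0.338). In N2 of the same set they were 17.97 ± 6.91 against 20.2 ± 9.39 TPM (log2 -0.10, SE 0.338, n = 5 each). Neither wild type change passed the test (adjusted p = 0.747 in WT and 0.873 in N2). The sign in N2 turned without the libraries rich in sperm transcripts (0.020), without all 5 libraries in doubt described with the N2 response (0.14), and without N2 at 50 mM replicate 2 (0.011) or 3 (0.10) or N2 at 300 mM replicate 3 (0.020).

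In the limma fits over all genes 0 of these 7 NaCl responses of hrg-1 passed the test, with 0.0536 in gcp109 as the smallest adjusted p. With the replicate block, where the numbers paired the libraries, hrg-1 passed in F1het (adjusted p = 0.0427), F1KO (0.0264) and gcp109 (0.0126). In set E this block also joined F1het with F1KO, between which the numbers were not taken to pair the libraries. The exact two-sided permutation test of hrg-1 alone gave p = 0.00794 in gcp100 (0.0397 adjusted over 15 comparisons), 0.0286 in gcp109 (0.107 adjusted) and 0.810 in N2. Without the libraries in doubt the change in gcp100 was 0.95 (2 against 5 libraries, exact permutation p = 0.0952, 0.210 adjusted over 6, where 0.0476 is the smallest possible before adjustment), so its call ended. With 3 libraries per group the smallest possible p is 0.1, which F1het and F1KO reached, and with 2 libraries it is 0.333. Leaving out 1 library at a time moved the limma adjusted p of hrg-1 both ways. It ranged from 0.0469 (without n4117 at 300 mM replicate 2) to 0.984 in n4117, where the log2 change was 1.24 without n4117 at 300 mM replicate 1. It ranged from 0.0226 (without F1het at 300 mM replicate 2) to 0.536 in F1het, from 0.0223 (without F1KO at 50 mM replicate 3) to 0.304 in F1KO, and from 0.0379 (without gcp109 at 50 mM replicate 4) to 0.170 in gcp109. In each of these 4 only 1 of the fits with a library left out passed.

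Between genotypes, hrg-1 was higher in gcp109 than in N2 at 300 mM (log2 1.52, SE 0.338, limma adjusted p = 0.0191, exact permutation p = 0.00794, 0.0397 adjusted). The limma call ended without gcp109 at 300 mM replicate 1 (0.0563) or replicate 3 (0.123), and without N2 at 300 mM replicate 3 (0.0508) or replicate 5 (0.0589). These strains belong to different sets, so batch and genotype cannot be told apart. The overlapping gene mop-25.1, whose reads may not be separated from those of hrg-1, was higher in gcp109 too (log2 0.63, SE 0.156, limma adjusted p = 0.03785). Within set G, hrg-1 in gcp100 stood above N2 at 300 mM by 0.90 on the log2 scale, with an exact permutation p of 0.00794 (0.0397 adjusted) and a limma adjusted p of 0.777. Without the 5 set G libraries in doubt, a choice made after the data were seen, this difference was 0.49 (2 against 3 libraries, limma adjusted p = 1, exact permutation p = 0.300, where 0.1 is the smallest possible, and 0.360 adjusted over 6). That between gcp109 and N2 at 300 mM was then 1.27 (4 against 3 libraries, exact permutation p = 0.0286, 0.171 adjusted over 6). For these sizes 0.0286 is the smallest possible exact permutation p before adjustment. At 50 mM gcp100 differed from N2 by -0.32 (exact permutation p = 0.421). In set D hrg-1 differed between n4117 and WT by 0.86 at 50 mM and 2.33 at 300 mM, with a limma adjusted p of 1 at both (from 0.0312 without n4117 at 300 mM replicate 2 to 1 over the fits that left out 1 library at 300 mM). In set E it differed between F1KO and F1het by 0.03 and 0.25 (exact permutation p of 0.900 and 0.500). The NaCl response of hrg-1 differed from that of the control by 1.47 in n4117, 0.22 in F1KO, 1.21 in gcp100 and 1.43 in gcp109. Permutation tests of these 4 differences gave p = 0.444, 0.595, 0.0282 and 0.0448, and 0.593, 0.595, 0.0896 and 0.0896 after adjustment over the 4. These tests assume no genotype difference at either exposure, which is stricter than equal NaCl responses. The values of gcp100 and gcp109 share the N2 libraries as control and are not independent. Without the 5 libraries in doubt the difference was 0.81 in gcp100 (permutation p = 0.166, 0.2495 adjusted over 6) and 1.19 in gcp109 (0.105, 0.210 adjusted).

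**Figure D1:**
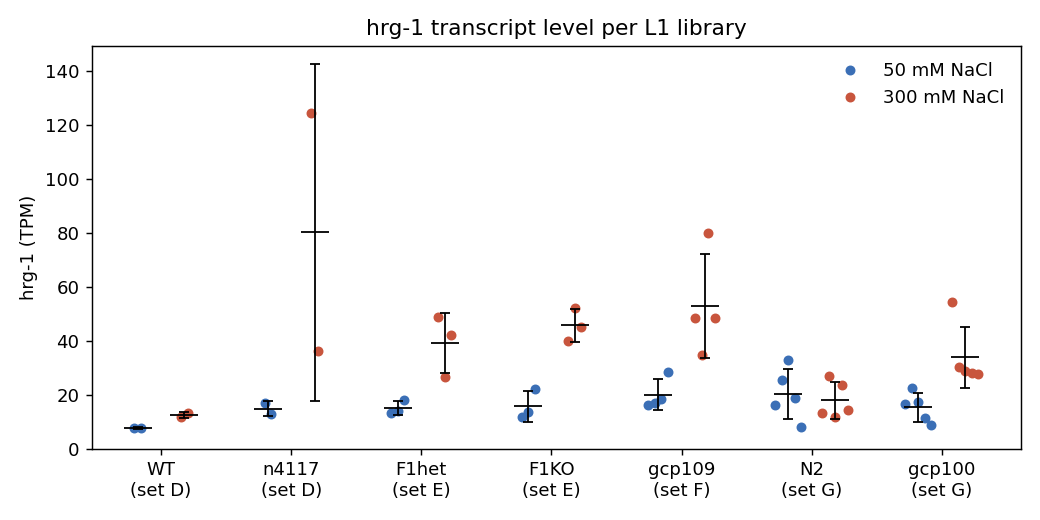
Level of hrg-1 in TPM (vertical axis) in each L1 library by strain and set, at 50 mM (blue) and 300 mM (red) maternal NaCl, with black bars for mean ± SD over 2 to 5 libraries. The 300 mM means lie above the 50 mM means except in N2 of set G, and in N2 of set G the libraries overlap, with means of 20.2 and 17.97 TPM.

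In the progeny of wild type mothers of set D the collagen gene col-108 stood at 71.7 ± 14.6 TPM at 300 mM against 2.25 ± 0.785 at 50 mM (log2 4.49, SE 0.389, adjusted p = 0.0735). The linker histone gene his-24 stood at 885 ± 57.3 against 201 ± 35.97 TPM (log2 2.15, SE 0.228, adjusted p = 0.105), and the flavin monooxygenase gene fmo-2 at 11.9 against 1.68 TPM. With 2 libraries per group 0 genes passed the limma test, and 1394 of 14969 had an unadjusted p under 0.05. Among the fixed lists, histones were higher (66 of 67 members, median log2 0.96, 0 called over all genes and 15 up adjusted over the list alone), with adjusted p = 0.527 with an estimated correlation. The 12 genes of the mitochondrial genome were all lower (median -0.62, 0 called over all genes and 0 adjusted over the list alone), again with adjusted p = 0.527 with an estimated correlation. Heat shock and chaperone genes had a median of -0.70 and pharynx markers of -0.81, both with adjusted p = 0.527 with an estimated correlation.

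In n4117 of the same set 3 genes rose and 4 fell at 300 mM. The collagen gene col-108 rose from 1.49 ± 0.0495 to 52.4 ± 28.7 TPM (log2 4.31, SE 0.389, adjusted p = 0.0309). ZK270.4 and EGAP3.2 were listed at 0 at 50 mM and stood at 17.8 ± 6.73 and 11.5 ± 2.70 TPM at 300 mM. The infection response gene F08G5.6 fell from 35.6 ± 6.11 to 1.75 ± 0.354 TPM (log2 -3.73, SE 0.305, adjusted p = 0.0305), and dod-24, a gene downstream of the insulin pathway factor DAF-16, fell from 50.5 ± 4.93 to 3.88 ± 0.778 TPM (adjusted p = 0.0309). T24B8.5 fell from 9.70 to 0.59 TPM and the C-type lectin gene clec-47 from 17.99 to 2.79 TPM. Histones had a median of 0.77 (67 members, 0 called over all genes and 10 up adjusted over the list alone), with adjusted p = 0.793 with an estimated correlation. Pharynx markers had a median of -1.94 (0 called over all genes and 7 down adjusted over the list alone), with adjusted p = 0.686 with an estimated correlation. At an unadjusted p under 0.05 there were 1827 genes. Rescaling shifted the median of all genes by -0.156 on the log2 scale, from 0.163 to 0.00665, and left 0 of the 7 calls. Without a filter 2 of the 7 were left, and with a pseudocount of 0.1 the calls of ZK270.4 (adjusted p = 0.138) and clec-47 (0.0825) ended. The replicate block left 2 of the 7, with 0 up and 2 down, so the calls of all 3 rises ended, though the numbers were not taken to pair these libraries. The count was 0 without n4117 at 50 mM replicate 1 or replicate 2, 33 without n4117 at 300 mM replicate 1 and 4 without replicate 2.

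In set E few genes passed the test. In F1KO the Vasa-type germline helicase gene glh-1 rose from 1.25 ± 0.200 to 5.74 ± 0.864 TPM (log2 1.58, adjusted p = 0.0136), and rpl-11.1, a ribosomal protein gene, rose from 55.5 ± 6.69 to 110 ± 3.21 TPM (log2 0.98, adjusted p = 0.0312). In F1het the values of these genes were 1.14 and 0.88, with an adjusted p of 0.0694 each. The other calls, chosen here after their values were seen, were C23H4.11 (listed at 0 at 50 mM, 3.44 ± 0.799 TPM at 300 mM) and C54H2.7 (4.08 ± 1.61 TPM, then listed at 0) in F1KO, and K02C4.9 (4.44 ± 1.40 TPM, then listed at 0) in F1het. The 12 genes of the mitochondrial genome were lower in every case, with a median of -0.60 in F1het (7 down adjusted over the list alone) and -0.69 in F1KO (11 down adjusted over the list alone), and 0 called over all genes. Their adjusted p with an estimated correlation was 0.733 in F1het and 0.335 in F1KO. Ribosomal protein genes were higher in 69 of 75 cases in F1het (median 0.27, 0 called over all genes and 1 up adjusted over the list alone, adjusted p = 0.794 with an estimated correlation).

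The NaCl responses of set E were thus 0 up and 1 down in F1het and 3 up and 1 down in F1KO, among 15454 genes, with 1757 and 1829 at an unadjusted p under 0.05. The numbers paired the libraries within each genotype (lowest r = 0.106, in F1het), which calls for a block. The block fitted also joined F1het with F1KO, between which the numbers were not taken to pair (lowest r = 0.0548, at 50 mM). With this block 54 genes rose and 116 fell in F1het. In F1KO 74 rose and 154 fell, and all 4 unblocked calls were kept. In F1het glh-1 and rpl-11.1 then passed (adjusted p = 0.0243 and 0.0246), as did the osmotic response list and pharynx markers, both lower, with camera (adjusted p = 0.0453 each, and 0.766 each with an estimated correlation). With a pseudocount of 0.1 all 4 unblocked calls in F1KO ended (adjusted p = 0.0617 for both glh-1 and rpl-11.1, 0.0869 for C23H4.11 and 0.0819 for C54H2.7), and after rescaling that of rpl-11.1 (0.0652). The count in F1het was 0 without F1het at 50 mM replicate 2 or 3, 0 without F1het at 300 mM replicate 1 or 3, and 121 without F1het at 300 mM replicate 2. In F1KO it was 9 and 36 without F1KO at 50 mM replicates 1 and 3, 0 without F1KO at 300 mM replicate 1 or 3, and 1 without replicate 2.

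The larvae of gcp109 mothers gave a broad NaCl response, with 93 genes up and 98 down. The collagen gene col-108 rose from 1.11 ± 0.579 to 68.0 ± 8.69 TPM (log2 5.06, SE 0.201, adjusted p = 2.13e-05, n = 4 each), and the fatty acid and retinol binding protein gene far-3 from 4.21 ± 2.74 to 69.2 ± 21.1 TPM (log2 3.84). The mitochondrial superoxide dismutase gene sod-3 rose from 2.62 ± 0.905 to 44.9 ± 8.03 TPM (log2 3.69, SE 0.224), fmo-2 from 4.80 ± 0.726 to 34.9 ± 14.4 TPM (log2 2.56, SE 0.245), and the inositol transporter gene hmit-1.1 from 26.4 ± 1.55 to 80.1 ± 23.02 TPM (log2 1.53, SE 0.176). The secreted heme chaperone gene hrg-3 rose from 0.287 to 4.58 TPM (log2 2.04, adjusted p = 0.0112). Among the genes that fell were dod-24, from 78.1 ± 36.5 to 4.15 ± 1.21 TPM (log2 -3.87, SE 0.296), dod-22 (log2 -3.46), F08G5.6 (log2 -3.31, SE 0.139), the C-type lectin genes clec-209 (log2 -3.11) and clec-45 (log2 -2.48), the acyl-CoA dehydrogenase gene acdh-2 (log2 -2.91), and hsp-4, the BiP chaperone of the endoplasmic reticulum (log2 -1.54, adjusted p = 0.00602). Each of these genes kept its call without any single library.

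By list, histones passed camera as higher in gcp109 (64 of 65 members positive, median 1.499, 5 up over all genes and 39 up adjusted over the list alone). Among them his-24 rose from 189 ± 61.4 to 706 ± 107 TPM. The adjusted p was 0.193 with an estimated correlation. Collagens passed as higher too (71 members, median 0.51, 11 up over all genes, 24 up and 1 down adjusted over the list alone), with col-159 (log2 2.07), col-145 (log2 2.11) and col-93 (log2 1.81) beside col-108, and with adjusted p = 0.419 with an estimated correlation. Hypodermis markers, of whose 11 members 5 are collagens, summed to 1220 ± 74.7 TPM at 300 mM and 802.5 ± 153.9 at 50 mM, with no overlap between libraries, and did not pass camera (adjusted p = 0.111). Effectors of innate immunity passed as lower (115 members, median -0.20, 8 down over all genes and 19 down adjusted over the list alone, adjusted p = 0.419 with an estimated correlation), led by clec-209, clec-45 and the lysozyme gene lys-7 (log2 -1.54). Fat metabolism genes passed as lower (29 members, median -0.24, 3 down over all genes and 5 down adjusted over the list alone, adjusted p = 0.187 with an estimated correlation), among them acdh-2 and the carnitine palmitoyltransferase gene cpt-1 (log2 -0.83, adjusted p = 0.0111, and 0.0553 without gcp109 at 50 mM replicate 3). Heme and iron genes passed as higher (18 members, median 0.19, 1 up over all genes and 3 up adjusted over the list alone, adjusted p = 0.257 with an estimated correlation), with hrg-3 as the member that passed. Germline markers (median 0.89) and maternal and early embryo markers (median 1.04) passed as higher and neuron markers (median -0.18) as lower, each with 0 called over all genes and 0 adjusted over the list alone, and with adjusted p = 0.626, 0.626 and 0.739 with an estimated correlation. The osmotic response list did not pass camera (23 members, adjusted p = 0.575), with 3 members up. The Microprocessor genes drsh-1 and pash-1 had values of 0.24 (adjusted p = 0.544) and 0.41 (0.563).

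At an unadjusted p under 0.05 there were 2103 of 14102 genes in gcp109. With the replicate block the count was 873 up and 892 down, and all 191 unblocked calls were kept. With the block antimicrobial peptide genes passed camera as higher (adjusted p = 0.0255, and 0.639 with an estimated correlation) and genes of the mitochondrial genome as lower (adjusted p = 0.0351, and 0.8075 with an estimated correlation). The count fell to 58 up and 50 down without gcp109 at 50 mM replicate 1, to 89 and 79 without replicates 2 and 3, and to 98 and 95 without gcp109 at 300 mM replicates 1 and 2.

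**Figure D2:**
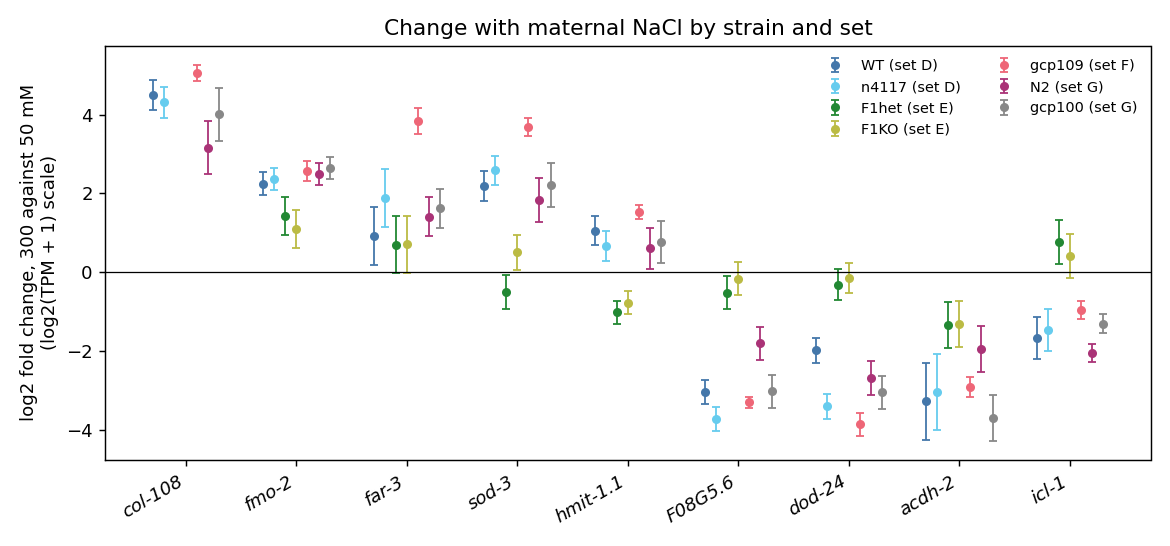
Log2 fold change at 300 against 50 mM maternal NaCl on log2(TPM + 1) (vertical axis) of 9 genes by strain and set, where points are limma estimates and bars their SE, with genes chosen partly after their values were seen. The collagen gene col-108, which was not among the tested genes of set E, lies at 5.06 in gcp109, and dod-24 lies at -3.87 in gcp109, -2.69 in N2 and -3.05 in gcp100.

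In N2 of set G 325 genes rose and 332 fell at 300 mM. Histone genes were among the largest rises. Transcripts of his-32 rose from 3.10 ± 1.44 to 214 ± 180 TPM (log2 5.23, SE 0.603, adjusted p = 6.94e-05, n = 5 each), and his-29 and his-34, whose values are identical and may share reads, from 1.19 to 128 ± 123 TPM. Of 69 histone genes 64 had positive values, 44 rose over all genes and 59 adjusted over the list alone (median 2.74, camera adjusted p = 1.66e-46), and the list held with an estimated correlation (adjusted p = 0.0313, and 0.1955 without the libraries in doubt). Collagens passed camera as higher too (90 members, median 0.59, 5 up over all genes and 6 up adjusted over the list alone) and held with an estimated correlation (adjusted p = 0.0313), among them col-92, which rose from 65.5 to 279 ± 86.0 TPM. The monooxygenase gene fmo-2 rose by 2.48 (SE 0.275, adjusted p = 6.94e-05).

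The glyoxylate cycle gene icl-1 fell in N2 from 1652 ± 470 to 397 ± 107 TPM (log2 -2.06, SE 0.235, adjusted p = 6.94e-05), and so did the trehalose phosphate synthase gene tps-2 (log2 -0.89), the fructose bisphosphatase gene fbp-1 (log2 -0.89), the AMP-activated kinase gene aak-2 (log2 -0.94) and cpt-1 (log2 -1.105). These 5 genes kept their calls without any single library. The gene dod-24 fell from 57.7 ± 27.2 to 9.11 ± 7.38 TPM (log2 -2.69, SE 0.422, adjusted p = 0.00118). The noncoding gene M60.15 fell from 17.6 ± 3.30 TPM to a listing of 0 in all 5 libraries. The L1 starvation list passed camera as lower (20 members, median -0.66, 1 up and 6 down over all genes, adjusted p = 0.160 with an estimated correlation), as did the heat shock and chaperone list (20 members, median -1.202, 2 down over all genes and 10 down adjusted over the list alone, adjusted p = 0.387 with an estimated correlation). The osmotic response list passed as lower (23 members, median -0.36, 1 down over all genes and 4 down adjusted over the list alone, adjusted p = 0.387 with an estimated correlation). The genes drsh-1 (1.24, adjusted p = 0.0934) and pash-1 (1.08, adjusted p = 0.273) did not pass.

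Transcripts of germline, sperm, early embryo and mother had higher means at 300 mM in N2. Mother soma markers summed to 2370 ± 4718 TPM at 300 mM (median 346, 10807 in replicate 3) against 169 ± 40.25 at 50 mM. Germline markers summed to 686 ± 954 TPM (median 236, 2368 in replicate 3) against 112 ± 22. In both lists the libraries of the 2 exposures overlapped. Both lists passed camera (adjusted p = 0.0012 and 4.45e-09), and neither held with an estimated correlation. Sperm markers passed camera as higher (30 of 30 members positive, median 2.69, 0 called over all genes and 23 up adjusted over the list alone, adjusted p = 0.291 with an estimated correlation). Markers of maternal and early embryo transcripts passed as higher (16 members, median 3.10, 3 up over all genes and 15 up adjusted over the list alone, adjusted p = 0.291 with an estimated correlation), among them pos-1, the gene of a maternal RNA-binding protein, which rose from 0.672 to 115 ± 189 TPM (log2 4.28, SE 1.15, adjusted p = 0.0403). The mitotic cyclin gene cyb-3 rose by 4.01 (SE 0.841, adjusted p = 0.0108). Vitellogenin and yolk genes had a median of 2.38 (12 members, 0 called over all genes and 3 up adjusted over the list alone, adjusted p = 0.413 with an estimated correlation), and the yolk protein gene vit-2 stood at 746 ± 1605 against 3.11 ± 4.75 TPM (log2 4.00, adjusted p = 0.250). Markers of larval tissues went different ways. Intestine markers summed to 5748 ± 1732 TPM at 300 mM and 5640.0 ± 2483 at 50 mM, and hypodermis markers to 993 ± 175 and 798.5 ± 221 TPM. Neuron markers summed to 2357 ± 1063 TPM at 300 mM and 3680 ± 282 at 50 mM (16 of 16 members lower, median -0.86, adjusted p = 0.435 with an estimated correlation). Pharynx markers summed to 862.5 ± 677 and 1818 ± 893 TPM (median -1.32, adjusted p = 0.536 with an estimated correlation), both lists with 0 called over all genes, and with 0 and 4 down adjusted over the list alone. Body wall muscle markers, at 12212 ± 5101 and 15108 ± 1960.5 TPM, did not pass camera (adjusted p = 0.0583). The sums were uneven between libraries, with neuron markers at 686 TPM in N2 at 300 mM replicate 3 and between 1997 and 3410 TPM in the others. The 6 vitellogenin genes summed to 7563 TPM in N2 at 300 mM replicate 3 and to 173.6, 11.2, 5.89 and 182 TPM in replicates 1, 2, 4 and 5. The call of pos-1 ended without any 1 of the 5 N2 libraries at 50 mM (adjusted p from 0.0693 to 0.0930), and without N2 at 300 mM replicate 1 (0.0704), replicate 3 (0.103) or replicate 5 (0.112), and without a filter (0.0713).

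Among 15275 genes 3733 had an unadjusted p under 0.05 in N2. The count was 286, 340, 370, 327 and 243 without N2 at 50 mM replicates 1 to 5, and 417, 1332 and 280 without N2 at 300 mM replicates 1, 4 and 5. In doubt were 3 set G libraries with over 50% of genes listed at 0 (N2 at 300 mM replicate 5 with 58.9%, gcp100 at 300 mM replicate 3 with 64.5% and replicate 5 with 59.9%), and 2 with over 0.1% of their TPM in major sperm protein genes (N2 at 300 mM replicate 3 with 0.475% and gcp100 at 300 mM replicate 1 with 0.150%). Without these 5 libraries, a choice made after the data were seen, 686 genes rose and 560 fell in N2, with 559 of the 657 calls kept.

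**Figure D3:**
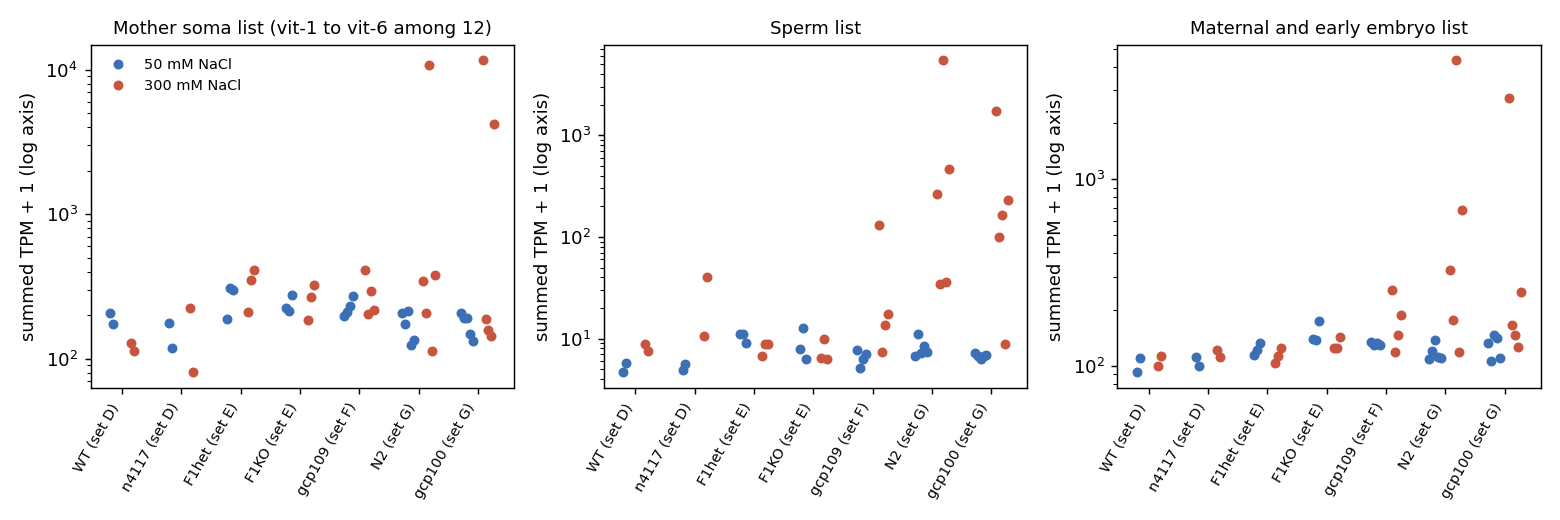
Summed TPM + 1 of the mother soma, sperm, and maternal and early embryo marker lists (vertical log axes, 1 panel per list) in each L1 library by strain and set at 50 mM (blue) and 300 mM (red) maternal NaCl. The means at 300 mM stand at 2370 TPM in N2 and 3260.0 TPM in gcp100 for mother soma and at 1256 TPM in N2 and 445 TPM in gcp100 for sperm markers, where single libraries stand far above the others.

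In gcp100 40 genes rose and 55 fell at 300 mM. The gene col-108 rose from 1.08 ± 0.294 to 41.4 ± 29.4 TPM (log2 4.00, SE 0.674, adjusted p = 0.00746), his-32 from 2.49 to 38.6 ± 23.4 TPM (log2 3.21, adjusted p = 0.0148), and fmo-2 from 2.91 to 23.8 ± 6.59 TPM (log2 2.63, SE 0.275, adjusted p = 9.54e-05). The gene dod-24 fell from 65.1 ± 33.2 to 6.87 ± 3.48 TPM (log2 -3.05, adjusted p = 0.00145), acdh-2 from 23.7 to 0.73 TPM (log2 -3.71, adjusted p = 0.00541), and icl-1 from 1630 ± 278 to 674 ± 199 TPM (log2 -1.31, adjusted p = 0.0101). Histones passed camera as higher (69 members, median 1.72, 12 up over all genes and 41 up adjusted over the list alone) and held with an estimated correlation (adjusted p = 0.0410, and 0.470 without the libraries in doubt), as did collagens (90 members, median 0.33, 5 up over all genes and 7 up adjusted over the list alone, adjusted p = 0.00564 with an estimated correlation). Neither list passed fry in gcp100 (adjusted p = 0.0565 and 0.192). With the replicate block only 1 list in gcp100 held with an estimated correlation, so at least 1 of these calls ended. Antimicrobial peptide genes passed camera as lower (21 members, median -0.87, 1 down over all genes and 5 down adjusted over the list alone, adjusted p = 0.288 with an estimated correlation), and heat shock and chaperone genes had a median of -1.40 (20 members, 0 called over all genes and 12 down adjusted over the list alone, adjusted p = 0.337 with an estimated correlation). Sperm markers were higher in 30 of 30 cases (median 1.99, adjusted p = 0.337 with an estimated correlation), and vit-2 stood at 1330 ± 2145 TPM, with vitellogenin sums of 10004 TPM in gcp100 at 300 mM replicate 1, 3773 in replicate 5 and between 2.08 and 4.84 in the others.

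At an unadjusted p under 0.05 there were 2003 genes in gcp100. The count was 34, 48, 57, 41 and 32 without gcp100 at 50 mM replicates 1 to 5, and 63, 44 and 54 without gcp100 at 300 mM replicates 1, 3 and 5. The calls of fmo-2 and dod-24 held in every case. The call of his-32 ended without gcp100 at 50 mM replicate 5 (0.0579). Without the 3 set G libraries with over 50% of genes listed at 0, 2 of them gcp100 libraries, the count was 18, and the adjusted p of col-108, his-32, acdh-2 and icl-1 was 0.0899, 0.0858, 0.0846 and 0.0899. Without all 5 libraries in doubt it was 68, with 27 of the 95 calls kept, and the adjusted p of his-32, acdh-2 and icl-1 was 0.175, 0.138 and 0.0680.

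Between n4117 and WT of set D, srw-85 (WBGene00005832), a gene for a serpentine receptor, was lower in n4117 at both exposures. It stood at 2.51 ± 0.262 against 87.8 ± 16.6 TPM at 50 mM (log2 -4.65, SE 0.209, adjusted p = 0.000632) and at 2.13 against 87.9 ± 4.57 TPM at 300 mM (log2 -4.83, adjusted p = 0.00048). R11H6.5 was lower too, at 0.13 against 12.31 ± 1.29 TPM (log2 -3.56, adjusted p = 0.0306) and at 0.26 against 17.1 ± 3.72 TPM (log2 -3.85, adjusted p = 0.0175). At 300 mM ZK270.4, listed at 0 in WT, was higher in n4117 (adjusted p = 0.0203). Pharynx markers stood lower in n4117 at 300 mM (median -1.26, 0 called over all genes and 1 down adjusted over the list alone, adjusted p = 0.784 with an estimated correlation), and heme and iron genes higher (19 members, median 0.18, 0 called over all genes and 2 up adjusted over the list alone, adjusted p = 0.784 with an estimated correlation). The counts were thus 0 up and 2 down at 50 mM and 1 up and 2 down at 300 mM, or 0 up and 2 down at 300 mM after rescaling, with 198 and 330 genes at an unadjusted p under 0.05. With a pseudocount of 0.1 the calls of R11H6.5 ended at both exposures (0.395 and 0.627), as did that of ZK270.4 (0.627). Only srw-85 was called without each library in turn. The call of R11H6.5 ended at 50 mM without WT replicate 1 (0.343) or 2 (0.634) and without n4117 replicate 1 (0.391) or 2 (0.592), and at 300 mM without WT replicate 1 (0.225) or 2 (0.327). The call of ZK270.4 ended without WT at 300 mM replicate 1 (0.333) or 2 (0.327) and without n4117 at 300 mM replicate 1 (0.0525), and at 300 mM 5 genes were called without n4117 replicate 2.

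F1KO larvae were compared with F1het larvae of the same heterozygous mothers. At 50 mM pes-10 was lower in F1KO (log2 -2.90, SE 0.337, adjusted p = 0.0245), and at 300 mM both pes-10 (log2 -4.02, adjusted p = 0.00191) and s65cGFP (log2 -3.34, adjusted p = 0.00474) were lower. The other calls, chosen after their values were seen, were C54H2.7, listed at 0 in F1het (adjusted p = 0.0143), and T18D3.10 (log2 -1.86, adjusted p = 0.0413) at 50 mM, and C23H4.11 (0.00328) and K02C4.9 (0.0061), both listed at 0 in F1het, at 300 mM. At 50 mM maternal and early embryo markers had a median of 0.57 and genes of the mitochondrial genome of 0.31, both with 0 called over all genes and adjusted p = 0.482 with an estimated correlation. At 300 mM collagens were higher in F1KO (90 members, median 0.44, 0 called over all genes and 1 up adjusted over the list alone, adjusted p = 0.726 with an estimated correlation). With a pseudocount of 0.1 the calls of C54H2.7 (0.205), T18D3.10 (1) and C23H4.11 (0.236) ended. The counts were 1 up and 2 down at 50 mM, or 1 and 1 after rescaling, and 2 up and 2 down at 300 mM, with 486 and 875 genes at an unadjusted p under 0.05. At 50 mM 0 genes were called without F1het replicate 1, 2 or 3 or F1KO replicate 2, and at 300 mM 8 without F1het replicate 2.

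Between gcp100 and N2 heat shock and chaperone genes stood higher in gcp100 at 50 mM (20 members, median 0.65, 0 called over all genes and 0 adjusted over the list alone, camera adjusted p = 1.54e-30), and this list held with an estimated correlation (adjusted p = 0.00309) but did not pass fry (adjusted p = 0.989). Its member hsp-16.2, a small heat shock protein gene, stood at 235 TPM in gcp100 and 123 ± 110 in N2 (log2 1.56, SE 0.580, adjusted p = 1). Nuclear genes of oxidative phosphorylation stood lower (32 members, median -0.17, 0 called over all genes, adjusted p = 0.396 with an estimated correlation, and 0.0494 with the replicate block and an estimated correlation). With the block heme and iron genes (adjusted p = 0.0233, and 0.695 with an estimated correlation) and ribosomal protein genes (6.22e-05, and 0.984) also passed camera as lower. This block also spanned the 300 mM libraries, whose numbers were not taken to pair. At 300 mM histones were lower in gcp100 than in N2 (69 members, median -1.07, 0 called over all genes and 22 down adjusted over the list alone, adjusted p = 0.294 with an estimated correlation), and heat shock and chaperone genes higher (median 0.65, 0 called over all genes and 8 up adjusted over the list alone, adjusted p = 0.419 with an estimated correlation). With limma 0 single genes passed at 50 mM and 0 at 300 mM, with 51 and 880 at an unadjusted p under 0.05. At 300 mM 1 gene was called without N2 replicate 5 or without gcp100 replicate 2.

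In gcp109 at 300 mM 181 genes stood higher than in N2 and 56 lower, or 136 and 72 after rescaling (76.4% and 65.4% higher). Small heat shock protein genes were among the higher ones. The gene hsp-16.41 stood at 335 ± 155 against 36.7 ± 29.7 TPM (log2 3.37, SE 0.642, adjusted p = 0.00712), and hsp-16.48 and hsp-16.49, which have identical values, at 963 ± 479 against 101 ± 78.7 TPM (log2 3.39, SE 0.634). C37A5.6 (log2 4.01, SE 0.668) and C37A5.5 (log2 3.84) were higher too, as were icl-1 (1164 ± 354 against 397 ± 107 TPM, log2 1.53, SE 0.246, adjusted p = 0.00198) and pck-1, which encodes the gluconeogenic enzyme PEPCK (2163 ± 521 against 840 ± 434 TPM, log2 1.503). Lower were H34I24.2 (log2 -3.95, SE 0.662, adjusted p = 0.00316), the histone genes his-32 (log2 -3.08) and his-30 (log2 -3.19), and the C-type lectin gene clec-266 (log2 -3.05). At 50 mM H34I24.2 was lower in gcp109 (log2 -4.05, SE 0.662, adjusted p = 0.0251), and ZK218.7, chosen after its values were seen, was higher (log2 1.46, adjusted p = 0.0251, and 0.834 with a pseudocount of 0.1), with 169 genes at an unadjusted p under 0.05.

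By list the heat shock and chaperone genes stood higher in gcp109 at 300 mM (20 members, median 1.72, 9 up over all genes and 12 up adjusted over the list alone, adjusted p = 0.139 with an estimated correlation). The L1 starvation list was higher (20 members, median 0.69, 4 up over all genes and 12 up adjusted over the list alone) and held with an estimated correlation (adjusted p = 0.0477). Antimicrobial peptide genes were higher (23 members, median 1.22, 4 up over all genes and 10 up adjusted over the list alone, adjusted p = 0.151 with an estimated correlation), and 19 of 19 heme and iron genes were higher (median 0.49, 1 up over all genes and 2 up adjusted over the list alone, adjusted p = 0.151 with an estimated correlation), with hrg-1 as the member that passed. Histones were lower (69 members, median -1.42, 14 down over all genes and 28 down adjusted over the list alone, adjusted p = 0.0673 with an estimated correlation), as were sperm markers (35 of 35 members, median -2.08, 0 called over all genes and 15 down adjusted over the list alone, adjusted p = 0.252 with an estimated correlation), which stood at 1256 ± 2369 TPM in N2 and 41.5 ± 59.5 TPM in gcp109.

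The gcp109 libraries belong to set F and the N2 libraries to set G, so batch and genotype cannot be told apart in any of these differences. Genes with an unadjusted p under 0.05 numbered 2885 at 300 mM. The count was 102, 80 and 55 without gcp109 at 300 mM replicates 1, 2 and 3, and 532, 453 and 114 without N2 at 300 mM replicates 2, 4 and 5. Without N2 libraries in doubt it was 224, with 128 of the 237 calls kept, and the adjusted p of hsp-16.41 was then 0.0745, of hsp-16.48 0.0588 and of hrg-1 0.112. Without gcp109 at 300 mM replicate 3 the adjusted p of pck-1 was 0.0689. At 50 mM the count of 2 became 0 without gcp109 replicate 2 or 3 or N2 replicate 1, 2 or 3, and 1 without N2 replicate 4 or 5.

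The difference of NaCl responses between a mutant and its control passed limma for 0 genes in n4117, F1KO, gcp100 and gcp109. At an unadjusted p under 0.05 there were 174, 369, 187 and 519 genes. Single calls arose without F1het at 50 mM replicate 1, F1het at 300 mM replicate 2 or F1KO at 300 mM replicate 3, and, for gcp109, without N2 at 300 mM replicate 4, 1 gene each. For heme and iron genes the median difference was 0.40 between n4117 and WT (19 members, camera adjusted p = 0.00281, and 0.928 with an estimated correlation) and 0.30 between gcp100 and N2 (camera adjusted p = 0.00267, and 0.433 with an estimated correlation). With 0 members called over all genes and 0 adjusted over the list alone, no stronger response of these genes was shown. For histones the median difference between gcp100 and N2 was -1.01 (69 members, 0 called over all genes, camera adjusted p = 6.46e-18, and 0.373 with an estimated correlation).

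The NaCl responses of the wild type in sets D and G, which share no library, correlated across genes with a Spearman coefficient of 0.482, and 595 of the 617 genes called in N2 and tested in both had the same sign in WT. Between F1het and WT the coefficient was 0.134, and between F1het and N2 0.167, with 406 of 619 called genes of the same sign. Genes are not independent replicates, so no p is given. Pairs chosen after the data were seen were gcp109 and N2, at 0.603, where 26 genes rose in both against 1.85 for independent lists and 34 fell in both against 2.24, and F1het and F1KO, at 0.510. For the differences between mir-85 mutants and their controls the coefficients at 50 mM were 0.136 between n4117 and F1KO, -0.137 between n4117 and gcp109 and -0.0553 between F1KO and gcp109. At 300 mM they were -0.0534, -0.231 and 0.0416, and the value between n4117 and gcp109 turned to 0.0250 without the libraries in doubt.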

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

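The tests of the patterns weighed here were chosen only after the results were seen, and the counts of other splits of the libraries were planned. In groups of 4 or 5 libraries, 144 sets of values were examined for a highest or lowest library far from the rest, and 23 had one. Chance gives about 1 in 20 for independent, normally distributed values. These were TPM without a log, and the sets share genes and libraries, so that rate is no fair measure of an excess here.

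In gcp109 at 50 mM replicate 4 was far from the other libraries for the summed TPM of intestine markers (8939 TPM) and of neuron markers (2743 TPM). In gcp109 at 300 mM replicate 1 stood apart for vitellogenin genes (160.2 TPM) and sperm markers (130.5 TPM), replicate 3 for fmo-2 (56.3 TPM) and replicate 4 for hmit-1.1 (114.2 TPM). In N2 at 50 mM replicate 2 stood apart for vitellogenin genes (28.1 TPM) and icl-1 (2464 TPM), and replicate 3 for dod-24 (104.7 TPM). In gcp100 at 50 mM replicate 4 stood apart for vitellogenin genes (17.6 TPM) and pos-1 (4.23 TPM).

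In N2 at 300 mM replicate 3 was far from the other libraries for vitellogenin genes (7563 TPM), mother soma markers (10807 TPM), sperm markers (5481 TPM), maternal and early embryo markers (4350.3 TPM), germline markers (2368 TPM), pos-1 (448.6 TPM) and dod-24 (21.8 TPM). In gcp100 at 300 mM replicate 1 was far from the others for sperm markers (1725 TPM), maternal and early embryo markers (2732 TPM), germline markers (1426 TPM), pos-1 (263.9 TPM) and hrg-1 (54.3 TPM).

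The first pattern weighed is that transcripts of mothers, sperm and early embryos stood high at 300 mM in set G. RNA of mothers or of another stage in single libraries is a candidate explanation for the yolk part, since the 3 highest of the 10 libraries held 98.2% of the vitellogenin TPM. Tests of germline, sperm, maternal and mother soma lists in N2 and gcp100 were repeated without the 5 libraries in doubt. By camera 7 of 8 were still called and up at the preset correlation, and 0 of 8 with an estimated correlation (adjusted p from 0.3905 to 0.9697). Sperm sums, however, were higher in every 300 mM library than in any 50 mM library of its strain. The lowest at 300 mM and the highest at 50 mM were 33.5 and 10.11 TPM in N2, and 7.85 and 6.13 TPM in gcp100. Zygotic embryo sums parted narrowly too (46.16 and 44.15 TPM in N2, 49.4 and 49.26 TPM in gcp100). Germline, maternal and mother soma sums overlapped, so for these a change in all 300 mM libraries stays open. For histones in N2 the values argue against the 5 libraries in doubt as the whole cause. Without these the median change was still 2.16, from 2.74, with 40 of 69 genes called. The list then did not hold with an estimated correlation (camera adjusted p = 0.1955). The N2 libraries kept at 300 mM also had sperm sums above all at 50 mM, so RNA of another stage is not excluded as a source. In gcp100 the histone median without the libraries in doubt was 0.98, with 1 gene called. Sums of zygotic embryo markers were higher at 300 mM outside set G too. The highest at 50 mM and the lowest at 300 mM were 42.85 and 60.06 TPM in WT. They were 43.79 and 50.27 TPM in n4117, and 43.59 and 44.7 TPM in gcp109. Sperm sums parted in WT (4.71 and 6.49 TPM) and n4117 (4.56 and 9.7 TPM), not in gcp109. In set E both sums had lower means at 300 mM, and its zygotic list includes pes-10. Their part in the NaCl calls was not tested.

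The second pattern is that hrg-1 in N2 of set G did not stand higher at 300 mM, while gcp100 of the same set did by 1.11 (SE 0.338), or 0.95 without the libraries in doubt (exact permutation p = 0.0952, 0.210 adjusted over 6). Rescaling hardly moved the N2 change, from -0.10 to -0.065 (SE 0.328), which argues against the scaling of the TPM as the reason. Without the libraries in doubt the N2 change was 0.14 (SE 0.384), still below that of gcp100. Its error leaves room for a rise as large as that in WT of set D (0.65). These libraries are therefore not excluded as part of the reason. Loss of mir-85 or of its site in hrg-1 could let hrg-1 rise more at 300 mM. Over sets D, E and G the mutants' rise exceeded that of their controls by 0.97 on average (SE 0.309), with a two-sided permutation p of 0.0900 over strain labels within each set, so this hypothesis is neither shown nor excluded. F1het larvae, which keep 1 copy of mir-85, also had high values at 300 mM.

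The third pattern is the low level of srw-85 in n4117 and in set E. Loss of mir-85 is argued against, since gcp109 differed from N2 at 50 mM by 0.21 (SE 0.426), and F1het libraries were low as well. A difference in strain background may account for it, as the highest of the 12 set E libraries stood at 3.56 TPM and the highest n4117 library at 2.69 TPM, while the lowest of the WT, N2, gcp109 and gcp100 libraries stood at 7.67 TPM (N2 at 300 mM replicate 3). No sequence of these strains was used here, so this remains a hypothesis.

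For the gene counts, other splits of the same libraries into groups of the same sizes were fitted. For N2 at 300 against 50 mM 1 of 100 splits gave as many calls, the real one (657, highest other 2), and for gcp100 1 of 100 (95, highest other 4). This is the smallest share the splits can give, so chance is an unlikely source of these counts but is not excluded. The libraries in doubt all lie at 300 mM, so the splits cannot tell their part from that of NaCl. For gcp109 against N2 4 of 100 splits gave as many at 300 mM (237, highest other 672) and 2 of 100 at 50 mM (2, highest other 2). The split with 672 calls set N2 replicates 1, 3, 4 and 5 against gcp109 with N2 replicate 2. It was thus the real split with 1 N2 library moved, and without that library the real count was 532. Chance is not taken as excluded for the counts of gcp109 against N2, since other splits also gave as many calls. At 50 mM the count was also 0 without any 1 of 5 libraries, and 7 unchanged genes were called in the simulation. For gcp109 at 300 against 50 mM 2 of 35 splits gave as many calls, so chance cannot be excluded by this count alone. The other was the split of replicates 1 and 2 from 3 and 4, with 2175 calls against the real 191, which follows the replicate numbers and parts 0 of the pairs. Among the 8 splits that part all pairs only the real one gave as many (highest other 2), and with the block the real split gave 1765 calls and the highest other 0.

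With 3 libraries per group there are 10 splits, too few for a share under 0.05. For F1het at 300 against 50 mM 3 of 10 splits gave as many calls (real 1, highest other 2), for F1KO 1 of 10 (real 4, highest other 1), for F1KO against F1het at 50 mM 2 of 10 (real 3, highest other 690, which points to a structure of the samples) and at 300 mM 1 of 10 (real 4, highest other 0). With the block, among the 4 splits that part all pairs, the real split gave 170 calls in F1het and 228 in F1KO and the highest other 0 in both. For counts of 0 every split gave as many, 100 of 100, with a highest other of 317 for the F1KO interaction, 1 and 2538 for gcp100 against N2 at 50 and 300 mM, 31 for the gcp100 interaction and 152 for the gcp109 interaction. At 300 mM 11 of the splits of gcp100 and N2 gave over 100 calls, which points to a structure of the samples other than genotype. The highest of these, with 2538 calls, parted exactly the 5 libraries in doubt from the other 300 mM libraries of set G. Among the 16 splits of gcp100 and N2 at 50 mM that part all pairs the highest other gave 1.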

How the results depend on the processing

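Leaving out set G libraries in doubt and reading set G with its names as deposited were chosen only after the data were seen, and the other alternatives were planned. For single named genes, 147 of 178 calls were kept with a pseudocount of 0.1, 142 without a filter, 157 after rescaling and 158 with the replicate block, and 0 called genes changed sign. Over all fits that left out 1 library, 1114 of 1553 such calls were kept and 0 changed sign. Of 197 list calls, 189 were kept with a pseudocount of 0.1, 168 without a filter, 187 after rescaling and 190 with the block, with 0 reversed, while leaving out 1 library kept 1602 of 1875 and reversed 35. The depth of each library is unknown, so its part in these changes could not be examined, and where no reason is given the cause was not tested. With 1 library left out of a group of 2, as in set D, limma pools the spread over groups and the lone library is assumed to vary like the others. The planned test of mir-85 seed sites, its stricter form by site type and the test of other seed sites were not run, because no genome sequence was used here.

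With a pseudocount of 0.1 the number of genes called was 1 for n4117 against WT at 300 mM, 2 for F1het at 300 against 50 mM, 0 for F1KO at 300 against 50 mM, 1 for the F1KO interaction, 1 and 2 for gcp100 against N2 at 50 and 300 mM, and 1 for gcp109 against N2 at 50 mM, and the Spearman coefficient of the NaCl responses of WT and N2 was 0.426. Without a filter more genes with low TPM were tested, and the number called was 16 in WT, 12 for n4117 against WT at each exposure, 6 in F1het, 5 and 9 for F1KO against F1het at 50 and 300 mM, and 6 for the F1KO interaction. The coefficients were then 0.0921 between WT and F1het, 0.352 between WT and N2, 0.1345 between F1het and N2, and, for the mir-85 differences at 300 mM, -0.0310 between n4117 and F1KO and -0.188 between n4117 and gcp109. After rescaling 0 genes were called in n4117 at 300 against 50 mM.

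With the replicate block the number called was 170 in F1het, 228 in F1KO, 1765 in gcp109, 1154 in N2 (651 of the 657 calls shared), 234 in gcp100 and 2 in n4117 at 300 against 50 mM, 1 for n4117 against WT at 50 mM, 7 for F1KO against F1het at 300 mM and 1 for gcp109 against N2 at 50 mM. In a balanced comparison the block cannot change the size of a response, so that of hrg-1 stood by design at 1.304 in F1het, 1.52 in F1KO and 1.33 in gcp109, and only its error could change, with which it passed the test in these 3. In gcp109 against N2 at 50 mM it went from 0.08 to -0.057, uncalled in both. The numbers were not taken to pair the libraries in WT (r = 0.196), n4117 (0.157), n4117 against WT (0.257 at 50 mM and 0.0364 at 300 mM), F1KO against F1het (0.0548 to 0.266 and 0.0721 to 0.269), N2 (-0.0120 to 0.250, 3 of 5 libraries closest to their own number), gcp100 (-0.0505 to 0.287, 2 of 5), gcp100 against N2 at 300 mM (-0.251 to 0.629, 3 of 5) and gcp109 against N2 (-0.432 to 0.386 and -0.292 to -0.123). In the paired comparisons the block lost 0 calls of named genes and gained 17 in F1het, 16 in F1KO, 30 in gcp109 and 0 in gcp100 against N2 at 50 mM. By camera it gained 6 list calls there, given beside these comparisons in the report, and lost 0. With an estimated correlation only nuclear oxidative phosphorylation in gcp100 against N2 changed, and the block changed no other call in the paired comparisons.

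Read with its names as deposited, which puts most values of set G on the wrong gene, gcp109 against N2 gave 10715 calls at 50 mM and 11104 at 300 mM, and 160 for the interaction. The camera adjusted p of intestine markers in gcp100 at 300 against 50 mM was 0.877, and in gcp109 against N2 at 50 mM it was 0.827 for antimicrobial peptides, 0.968 for detoxification, 0.916 for the insulin and dauer pathway and 0.004805 for body wall muscle, at 300 mM 0.988 for small RNA machinery, and in the interaction 0.594 for vitellogenin and yolk and 0.594 for maternal and early embryo markers, each with the direction reversed. The coefficients were 0.269 between WT and N2, 0.103 between F1het and N2, -0.0557 and -0.0617 between n4117 and gcp109 at 50 and 300 mM, and -0.0224 and 0.0113 between F1KO and gcp109. Of 913 single gene values 46 were reversed under this reading, because they then belong to other genes.

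Without libraries with over 50% of genes at 0, gcp100 at 300 against 50 mM gave 18 calls, and hypodermis markers in gcp100 against N2 at 300 mM reversed, with a camera adjusted p of 0.0330. Without the libraries richest in sperm transcripts gcp100 gave 176 calls, and hrg-1 in N2 at 300 against 50 mM went from -0.10 to 0.020. Without all 5 libraries in doubt N2 gave 1246 calls, hrg-1 in N2 went to 0.14 and hrg-1 in gcp109 against N2 at 300 mM to 1.27, uncalled (adjusted p = 0.112), and 1 gene was called for the gcp109 interaction. Within set G the difference of hrg-1 between gcp100 and N2 at 300 mM went from 0.90 to 0.49 (exact permutation p from 0.00794 to 0.300) and that of its NaCl responses from 1.21 to 0.81 (permutation p from 0.0282 to 0.166). Without the libraries richest in sperm transcripts alone these were 0.60 and 0.91, and without those with over 50% of genes at 0 they were 0.97 and 1.28. With all 5 left out list directions reversed for vitellogenin and yolk (camera adjusted p = 0.886) and mother soma (0.728) in gcp100, for antimicrobial peptides in gcp100 against N2 at 300 mM (0.00223) and in the gcp100 interaction (0.506), for ribosomal proteins in the gcp100 interaction (0.0006585), and for body wall muscle in gcp109 against N2 at 300 mM (0.660). The coefficients were then 0.579 between WT and N2, 0.132 between F1het and N2, and 0.0250 between n4117 and gcp109 at 300 mM, reversed from -0.231.

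Leaving out 1 library at a time gave ranges of calls of 0 to 33 in n4117 at 300 against 50 mM, 1 to 1 and 1 to 5 for n4117 against WT at 50 and 300 mM, 0 to 121 in F1het, 0 to 36 in F1KO, 0 to 3 and 3 to 8 for F1KO against F1het, 0 to 1 for the F1KO interaction, 79 to 169 in gcp109, 243 to 1332 in N2, 32 to 139 in gcp100, 0 to 1 for gcp100 against N2 at 300 mM, 0 to 2 and 55 to 532 for gcp109 against N2, and 0 to 1 for the gcp109 interaction. The log2 change of hrg-1 ranged from 1.24 to 3.00 in n4117 at 300 against 50 mM, from 1.45 to 3.21 for n4117 against WT at 300 mM, from 1.13 to 1.55 in F1het, from 1.34 to 1.79 in F1KO, from -0.23 to 0.21 for F1KO against F1het at 50 mM, from -0.026 to 0.48 for the F1KO interaction, from 1.11 to 1.51 in gcp109, from -0.38 to 0.10 in N2, and from -0.19 to 0.28 and 1.299 to 1.69 for gcp109 against N2.

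For lists the camera adjusted p is given as a range where leaving out 1 library reversed a direction. For n4117 against WT at 50 mM it ranged from 0.00044 to 0.129 for heat shock, 0.00112 to 0.459 for antimicrobial peptides, 0.00908 to 0.0661 for the mitochondrial genome, 6.96e-25 to 0.474 for histones and 3.98e-05 to 0.300 for body wall muscle, and at 300 mM from 0.000143 to 0.790 for neurons, 9.68e-06 to 0.789 for immunity, 0.0133 to 0.372 for oxidative phosphorylation and 1.395e-09 to 0.880 for germline. In WT it ranged from 0.0491 to 0.0959 for neurons, and in n4117 at 300 against 50 mM from 6.195e-08 to 0.849 for germline, 4.41e-07 to 0.996 for immunity, 0.0158 to 0.387 for ribosomal proteins and 0.0466 to 0.383 for oxidative phosphorylation. For the n4117 interaction it ranged from 2.73e-15 to 0.791 for histones and 0.000283 to 0.950 for immunity. In set E it ranged from 5.36e-05 to 0.938 for heat shock in F1het, from 2.38e-12 to 0.782 for ribosomal proteins in the F1KO interaction, and for F1KO against F1het at 50 mM from 0.00781 to 0.921 for antimicrobial peptides, 6.35e-08 to 0.995 for ribosomal proteins, 6.26e-09 to 0.921 for histones and 1.82e-06 to 0.876 for collagens. In set G it ranged from 7.71e-08 to 0.945 for the mitochondrial genome in gcp100 against N2 at 50 mM, and at 300 mM from 0.000174 to 0.842 for body wall muscle, 5.77e-05 to 0.7425 for germline, 0.000148 to 0.542 for sperm and 0.04565 to 0.8845 for mother soma. For the gcp100 interaction it ranged from 3.10e-05 to 0.864 for germline and 4.87e-05 to 0.855 for sperm.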

Other observations

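The values here were chosen only after they were seen and were not tested further. In set E some transcripts stood at levels apart from those of the other sets. The inositol transporter gene hmit-1.1 stood at 2.36 ± 1.21 TPM in F1het and 2.85 ± 0.0520 in F1KO at 50 mM (n = 3 each), against 23.9 to 32.95 TPM in the groups of the other sets at 50 mM. At 300 mM hmit-1.1 stood at 0.597 ± 0.224 and 1.32 ± 0.739 TPM in set E and between 47.2 and 80.1 TPM elsewhere. The gene F08G5.6 stood between 1.21 and 3.06 TPM in the 4 groups of set E, against 14.2 to 43.5 TPM in the groups of the other sets at 50 mM, while at 300 mM the others stood between 1.62 and 4.35 TPM, which overlaps the range of set E. Hypodermis markers summed to 170 to 268 TPM in set E and to 799 to 1379 TPM in the other groups. Set and strain background cannot be told apart for these levels.

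H34I24.2 (WBGene00019261, chromosome III 2842044 to 2845197) was called lower in gcp109 than in N2 and in no NaCl comparison in which it was tested, and its levels in other strains were not called different. It stood at 0.5 TPM in WT, 0.0975 in gcp109 and 0.08 in gcp100 at 50 mM, and at 16.8 ± 10.3 TPM in n4117, 30.3 in F1het, 30.9 in F1KO and 24.1 ± 18.6 in N2. WT of set D and N2 of set G carry the same strain label, N2, and their levels of this gene were not compared by a test. Genes of the mitochondrial genome stood lower at 300 mM for 12 of 12 members in each of WT, n4117, F1het, F1KO and gcp100, for 11 of 12 in N2 and for 10 of 12 in gcp109. By camera without the block the list was called in WT, n4117, F1het and F1KO and not in gcp109, N2 or gcp100. With an estimated correlation it was called in 0 of these (adjusted p = 0.527 in WT, 0.793 in n4117, 0.733 in F1het and 0.335 in F1KO). The difference between these sets was not tested.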
